A study of Mus musculus with 3 samples.

How the data were processed

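Hearts of wild-type mouse embryos (strain Black-Swiss) at day 12.5 of development were cross-linked with 1.5% formaldehyde for 10 minutes, per the labels' protocols. Chromatin was sheared to about 200 bp and precipitated with 4 μg of a rabbit antibody against HIF1α, and 10 ng of the recovered DNA went into each sequencing library. The labels name 2 HIF1α pulldown replicates and 1 input. They do not say whether the replicates came from separate pools of embryos, nor the sex of the embryos.

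Reads were processed with Bowtie2 and HOMER on the mm10 build, per the submitters' processing notes, which give no versions. The deposited file is 1 merged peak list made by the authors from peaks of both pulldowns, each called against the input, per the file headers. The header line names more columns than the file holds: the columns kept are position, name, score and strand. The deposited score is a whole number of at least 2, and the header does not say what it is relative to. It was therefore used only to describe, rank and filter peaks within the list. The calling threshold and the rule for merging are not given in the sources used here.

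Each peak name ends in 1 or 2, which was read as the number of merged calls, after the header's total of subpeaks. All 15300 peaks ending in 1 are 101 bp wide, and peaks ending in 2 are 101 to 201 bp wide with a median of 122 bp, as a merge of overlapping windows of that width would give. The replicate a single call came from is not marked and was not inferred. If calls were split evenly between the pulldowns, 20.6% of the calls of each would have a partner in the other. Both sets of calls were made against the same input, so part of this overlap may come from that shared control. No library sizes, read counts or input values were used here, so the depth is unknown. Intervals are exact 95% Clopper-Pearson intervals over peaks or genes, and peaks and genes are not biological replicates.

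Gene positions and symbols came from a RefSeq gene table of assembly GRCm38.p6, the same build as mm10. The table gives the start and end of each gene but not its strand, exons or transcripts, and no genome sequence was used. A peak centre was therefore placed against either end of a gene in place of the transcription start site, so a peak at the 3' end counts like a peak at a promoter. Locations were reduced to within 1 kb of a gene end, inside a gene, or between genes, and positions are not resolved into exon, intron or UTR. Distances run from the peak centre to the nearest gene end. Of the annotated genes, 340 below 3 Mb on chromosomes other than Y were left out as belonging to unplaced sequence, where 0 peaks lie, and 17 had no chromosome. This left 49640 genes, of which 21779 nuclear genes are protein-coding. Of these, 5222 (24.0%) were near a peak and 1682 (7.72%) near a peak of 2 calls. The planned tests of the HIF binding motif, of its position, of 20 fixed motifs and of motif against score need sequence and were not run. The span from the first to the last gene stood in for the sequenced length of each chromosome.

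A protein-coding gene was called near a peak when a peak centre lay within 5 kb of either end. Each of 19 gene lists fixed before the data were examined was compared with all other protein-coding genes by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over lists, at a threshold of 0.05. All 435 listed symbols that were looked up matched a gene of the table. Shares of location classes were compared with 1000 random placements of the peaks on their own chromosomes, with a two-sided permutation p. Shares of peaks per chromosome were compared with shares of the span by a two-sided exact binomial test. Values for peaks of 2 merged calls were added after the file was seen.

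Genes were named by a rule fixed before the data were examined. From each list it took up to 4 genes near a peak, those with the smallest distance to a peak centre. It always took Hif1a, Epas1, Arnt, Vhl, Vegfa, Pdk1, Ldha, Pgk1, Slc2a1, Egln1, Egln3, Bnip3, Ankrd37, Hand1, Trp53, Atf4, Ddit3, Ccnd2, Mycn and Nkx2-5. It also took the 10 protein-coding genes with most peak centres within 50 kb and the 10 peaks with the highest score.

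Alternatives covered the window (500 bp, 1 kb, 5 kb and 50 kb), assignment of each peak to its nearest gene, protein-coding ends alone, any overlap, scores of at least 3, peaks of 2 calls, peaks inside genes, random placement by moving each peak 50 to 500 kb to either side, a background matched on gene length and gene density, and joining of neighbouring peaks. The median score equals the lowest score, so the planned higher-scoring part of the list was taken as scores of at least 3.

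The list test was tested on simulated peaks placed at random over 21779 genes, with peaks added at 80% of the genes of 8 lists of 25 genes each. It recovered 8 of the 8 lists at an adjusted p under 0.05 (Fisher exact test, adjusted over these 8). The added excess was large and the background evenly placed, so this does not show the power for smaller differences. Of 200 lists without added peaks, 4 had an unadjusted p under 0.05 (Fisher exact test). For the location test, a simulated set of 17288 randomly placed peaks gave a permutation p of 0.383. Distances and gene membership were checked against direct enumeration. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. One gene of a list added after the data were seen is not reported here by name.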

Results

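Loci bound by HIF1α were profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in wild-type mouse hearts at E12.5, the embryonic day at which they were dissected. HIF1α is the oxygen-regulated subunit of the hypoxia-inducible factor, which forms a dimer with ARNT and activates genes of the response to low oxygen. There were 3 libraries: 2 replicate HIF1α pulldowns and 1 input, which is chromatin without immunoprecipitation. The measurement analysed was the authors' merged list of 17289 peaks on the mm10 build, with a whole-number score for each peak. Of these, 15300 came from 1 call and 1989 (11.5%) from 2 merged calls. The read depth of the libraries is unknown from this list, and which pulldown gave a single call is not marked, so no value below has a replicate error. Intervals are exact 95% Clopper-Pearson intervals and cover counting error only.

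The main question set by the design was which genes lie near sites bound by HIF1α. Genes of the hypoxia response and of glycolysis lay near peaks far more often than other protein-coding genes. In the list of canonical hypoxia response and HIF feedback genes, 22 of 25 (88.0%, interval 68.8 to 97.5%) had a peak centre within 5 kb of either gene end, against 23.9% of other genes. In the list of glycolysis and glucose uptake genes, 17 of 22 (77.3%, interval 54.6 to 92.2%) did so, against 23.9% of other genes. The adjusted p was 2.2e-10 for hypoxia and 1.3e-06 for glycolysis (two-sided Fisher exact test, Benjamini-Hochberg over 19 lists).

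Most of these genes were marked by peaks of 2 merged calls. With that subset alone, 21 of 25 hypoxia genes and 16 of 22 glycolysis genes were near a peak, against 7.64% and 7.66% of other genes (adjusted p = 3.5e-19 and 4.5e-13, Fisher exact test). Ndrg1 and Eno3 were near peaks of 1 call alone. The hypoxia genes without a peak in the window were Car9, Egln3 and Kdm4c. The glycolysis genes without one were Slc2a3, Pfkm, Pfkfb3, Hk1 and Pfkfb4. These exceptions are named because their number was small, not by the rule for named genes. Some of them hold a peak deeper inside the gene. When peaks inside genes were also counted, 21 of 22 glycolysis genes (95.5%) and 23 of 25 hypoxia genes (92.0%) had a peak. The share of other genes was then 32.6%.

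Among hypoxia genes, the peak closest to a gene end was at Higd1a, 35 bp from the end and with a score of 13. Egln1, which encodes a prolyl hydroxylase that marks HIF1α for degradation, had a peak of score 19 at 47 bp (chromosome 8, 124949248 to 124949354). P4ha2, a collagen prolyl hydroxylase subunit, had a peak of score 14 at 68 bp. Ero1a, an oxidase of the endoplasmic reticulum, had one of score 16 at 77 bp. Ankrd37 carried a peak of score 100 inside the gene, 339 bp from its end (chromosome 8, 46000023 to 46000128). Bnip3, a mitophagy receptor, had 2 peaks of 2 calls within 5 kb, and the nearer one scored 36 at 120 bp. At Vegfa, which encodes a growth factor for blood vessels, the peak scored 10 and lay inside the gene, 1321 bp from its end (chromosome 17, 46030994 to 46031118). Egln3 was outside the 5 kb window, but a peak of 2 calls with a score of 53 lay inside the gene, 11.7 kb from its nearest end (chromosome 12, 54192068 to 54192187).

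Glycolysis genes carried some of the higher scores in the list. Pdk1, whose kinase restrains the use of pyruvate within the mitochondrion, had a peak of score 59 at 64 bp from its end (chromosome 2, 71873227 to 71873332). Pgam1 (phosphoglycerate mutase) had a peak of score 55 at 99 bp, and Pgk1 (phosphoglycerate kinase), on chromosome X, had one of score 25 at 151 bp. Eno1 (enolase) held the tenth highest score of the whole list, 109, in a peak inside the gene 224 bp from its end. At Aldoc (aldolase C) a peak of score 5 lay 18 bp from the gene end. Gapdh and the glucose transporter gene Slc2a1 each had 3 peaks of 2 calls within 5 kb. The nearest scored 18 at 146 bp for Gapdh and 17 at 362 bp for Slc2a1. The lactate dehydrogenase gene Ldha had a single peak in its window, with a score of 30, inside the gene 3505 bp from its end.

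**Figure D1:**
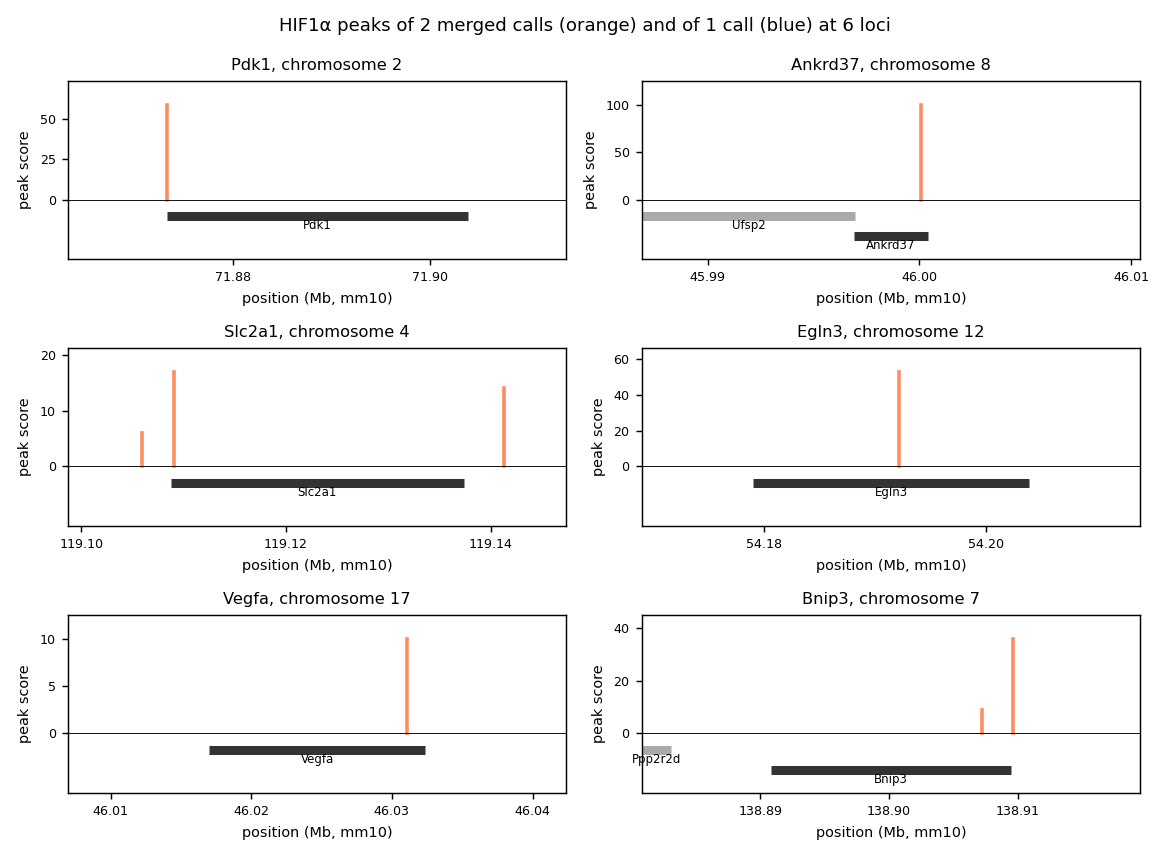
Peaks at 6 loci: each panel shows genomic position in Mb (mm10) against the deposited peak score, with orange lines for peaks of 2 merged calls, blue for 1 call, a dark bar for the named gene and grey bars for neighbouring protein-coding genes. The peaks of Pdk1 (score 59), Ankrd37 (100) and Bnip3 (36) stand at a gene end, whereas the peak of Egln3 (53) lies inside the gene, 11.7 kb from its nearest end.

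Genes of the HIF machinery itself differed in their peaks. Hif1a had a peak of 2 calls with a score of 13, 2354 bp beyond the gene (chromosome 12, 73949846 to 73949971). Arnt had a peak of 2 calls with a score of 4 at 187 bp. Epas1, which encodes HIF2α, had a peak of 1 call with a score of 3 at 445 bp. Vhl, which encodes the ubiquitin ligase subunit that recognises hydroxylated HIF1α, had 2 peaks in its window, both of 1 call, and the nearer one scored 5 at 7 bp.

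The list of unfolded protein and integrated stress response genes also lay near peaks more often than other genes. Of its 30 genes, 14 (46.7%, interval 28.3 to 65.7%) were within 5 kb, against 23.9% of other genes (adjusted p = 0.0393, Fisher exact test). Members included Trib3 (score 3 at 107 bp, 2 calls), Ppp1r15a (5 at 198 bp, 2 calls), Shmt2 (13 at 292 bp, 2 calls) and Atf4 (4 at 156 bp, 1 call). The peak counted for Shmt2 lies outside that gene and inside its neighbour Ndufa4l2, a member of the respiratory chain list, 323 bp from the end of that gene. Ddit3, which encodes the transcription factor CHOP, had its nearest peak 15.5 kb away. The call was lost with peaks of 2 calls alone, where 5 of 30 genes (16.7%) were near against 7.71% of other genes, with an adjusted p of 0.245 (Fisher exact test). It was lost under 4 more of the settings tried.

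The olfactory receptor genes, a family read out in sensory neurons, lay near peaks less often than other genes. Of 1109 genes, 108 (9.74%, interval 8.06 to 11.6%) were near a peak, against 24.7% of other genes (adjusted p = 2.9e-34, Fisher exact test). Only 2 of the 1109 were near a peak of 2 calls. The members closest to a peak were Olfr843 (19 bp), Olfr1047 (59 bp), Olfr1151 (82 bp) and Olfr855 (193 bp), all with peaks of 1 call and scores of 2 or 3. Within 1 kb of any peak lay 2.25% of the family, against 2.62% of all protein-coding genes in 5 random placements. The lower share is thus relative to other genes, and at 1 kb it was close to random placement. The test treats genes as independent, although neighbours can share a peak.

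Growth and mitochondrial lists lay above the background share without passing the adjusted threshold. Cytosolic ribosomal protein genes were near a peak in 12 of 28 cases (42.9%), with an adjusted p of 0.0986 (Fisher exact test). Rpl5 (15 bp), Rpl10a (21 bp), Rpl27 (53 bp) and Rpl18 (57 bp) had peaks of 2 calls with scores of 4 to 7. The ribosomal protein list did pass at a window of 1 kb, where 39.3% of its genes were near a peak (adjusted p = 0.0113, Fisher exact test). Respiratory chain genes were near a peak in 11 of 26 cases (42.3%, adjusted p = 0.118, Fisher exact test). Among them, Ndufs1 (172 bp) had a peak of 2 calls, and Cox7a1 (58 bp), Ndufb5 (67 bp) and Cycs (184 bp) had peaks of 1 call. With peaks of 2 calls alone, 4 of the 26 (15.4%) were near, against 7.71% of other genes (adjusted p = 0.289, Fisher exact test). For cell cycle drivers and replication genes the count was 12 of 32 (37.5%, adjusted p = 0.2, Fisher exact test). Aurka, a mitotic kinase gene, had a peak of 2 calls with a score of 13 at 37 bp, and Mcm3, a replicative helicase subunit gene, one of score 4 at 69 bp. The nearest peak was 13.3 kb from Ccnd2 and 17.2 kb from Mycn.

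Autophagy and mitophagy genes were near a peak in 10 of 23 cases (43.5%, adjusted p = 0.125, Fisher exact test). With peaks of 2 calls alone the list passed, at 6 of 23 (26.1%) against 7.7% of other genes (adjusted p = 0.0321, Fisher exact test). Of these 6 genes, Bnip3 and Bnip3l also belong to the hypoxia list, and the rest were Map1lc3b, Gabarap, Atg9a and Sqstm1. Genes of the p53 pathway and cell cycle inhibitors were near a peak in 8 of 24 cases (33.3%, adjusted p = 0.492, Fisher exact test). Bax had a peak of 2 calls with a score of 6 at 34 bp, whereas the nearest peak to Trp53 was 33.4 kb away. For fatty acid oxidation and mitochondrial biogenesis genes the count was 7 of 25 (28.0%, adjusted p = 0.8, Fisher exact test), with Nrf1 at 10 bp and Fabp3 at 761 bp, both with peaks of 2 calls.

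Genes that define heart cells were not found to differ from other genes in this test. Cardiac transcription factors were near a peak in 7 of 28 cases (25%, adjusted p = 0.828, Fisher exact test). None of the 28 was near a peak of 2 calls, and the exact interval of that share reaches 12.3%. Nkx2-5, an early regulator of cardiac muscle, had a peak of 1 call with a score of 19 at 372 bp (chromosome 17, 26844566 to 26844666). Such a score is rare without a second call: 10 of the 15300 peaks of 1 call scored 10 or more. Tbx3 (131 bp), Gata4 (142 bp) and Srf (475 bp) had peaks of 1 call with scores of 2 to 4. The nearest peak to Hand1 was 119 kb away. Sarcomere and calcium handling genes were near a peak in 8 of 30 cases (26.7%, adjusted p = 0.8, Fisher exact test), including Ttn (546 bp) and Actc1 (896 bp), both with peaks of 1 call. The 3 of them near a peak of 2 calls were Myh7, Tpm1 and Myl7, named here after their values were seen, and the peak of Myh7 scored 37.

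Lists of markers of other cell types and tissues, and of growth factors, did not pass the test at 5 kb, where about 24.0% of other genes were near a peak. The counts were 2 of 20 for endothelial and endocardial markers (Tie1 and Notch1), 1 of 14 for epicardial markers (Krt19) and 1 of 20 for cushion mesenchyme and smooth muscle markers (Snai2). Erythroid and blood markers gave 5 of 18, with Tfrc, the transferrin receptor gene, carrying a peak of 2 calls and score 14 at 11 bp. Angiogenic and growth factor genes gave 3 of 27, namely Vegfa, Tgfb2 and Bmp10. In the lists from other tissues, 4 of 20 neuronal genes and 3 of 20 liver genes were near a peak. The liver genes were the apolipoprotein genes Apoa1, Apoa2 and Apoc3, and Apoa1 and Apoc3 shared 1 peak. Adjusted p-values of these 7 lists were 0.148 or more (Fisher exact test). The angiogenic list passed at a window of 1 kb, where none of its genes was near a peak (adjusted p = 0.0497), and the liver list at 50 kb, with a lower share of 30.0% (adjusted p = 0.018, both Fisher exact tests).

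**Figure D2:**
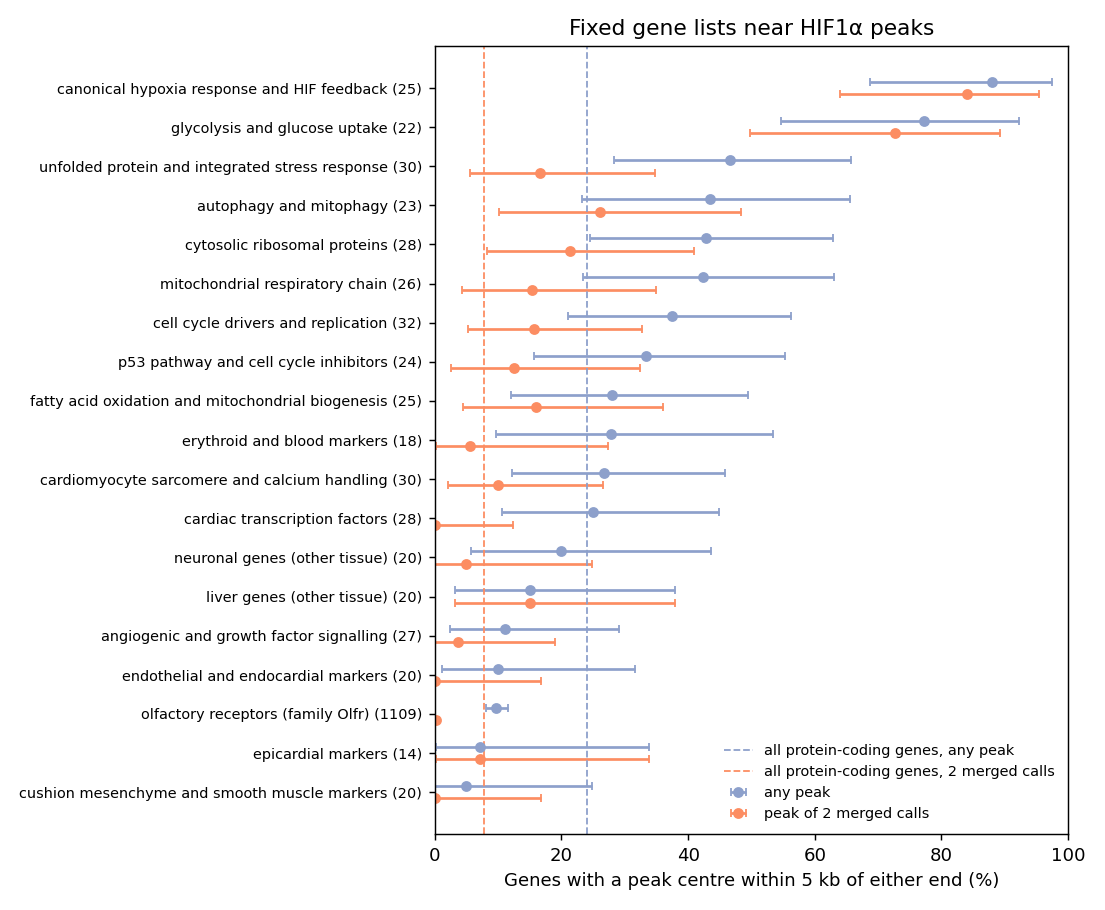
Share of each fixed gene list with a peak centre within 5 kb of either gene end, in percent, with the number of genes in parentheses; blue points are all peaks, orange points are peaks of 2 merged calls, bars are exact 95% intervals and dashed lines are the shares of all protein-coding genes (24.0% and 7.72%). The hypoxia (88.0%) and glycolysis (77.3%) lists stand apart from the rest with both sets of peaks.

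A further question was where the peaks lie relative to genes. Peaks were concentrated near gene ends. Of 17288 nuclear peaks, 3956 (22.9%, interval 22.3 to 23.5%) had their centre within 1 kb of a gene end. In 1000 random placements on the same chromosomes this share was 6.28% ± 0.179 (SD over placements), so the observed share was 3.64 times higher (two-sided permutation p = 0.001, the smallest these placements can give). Peaks inside genes and over 1 kb from an end were fewer than in random placements (32.3% against 44.9%), as were peaks between genes (44.8% against 48.9%), both with the same permutation p of 0.001. Each peak falls in a single class, so the excess at gene ends by itself lowers the other shares. These deficits are therefore not separate findings.

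Peaks of 2 merged calls lay near gene ends more often than the list as a whole. Their share within 1 kb of a gene end was 57.2% (interval 55.0 to 59.4%), which is 8.83 times that of random placements. For peaks of 1 call the share was 18.4%, or 2.94 times random, and their share between genes, 48.5%, could not be told from the 48.9% of random placements (permutation p = 0.3). That share between genes is likewise not independent of the share at gene ends. Within peaks of 1 call the position depended on the score. Counting ends of protein-coding genes, 4.62% of the 9570 nuclear peaks of 1 call with a score of 2 lay within 1 kb. That share was 24.8% of 4472 peaks at a score of 3 and 57.8% of 1257 peaks at scores of 4 or more. Peaks of 2 calls ranged from 41.7% at scores of 2 or 3 to 57.6% at scores of 4 or 5.

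**Figure D3:**
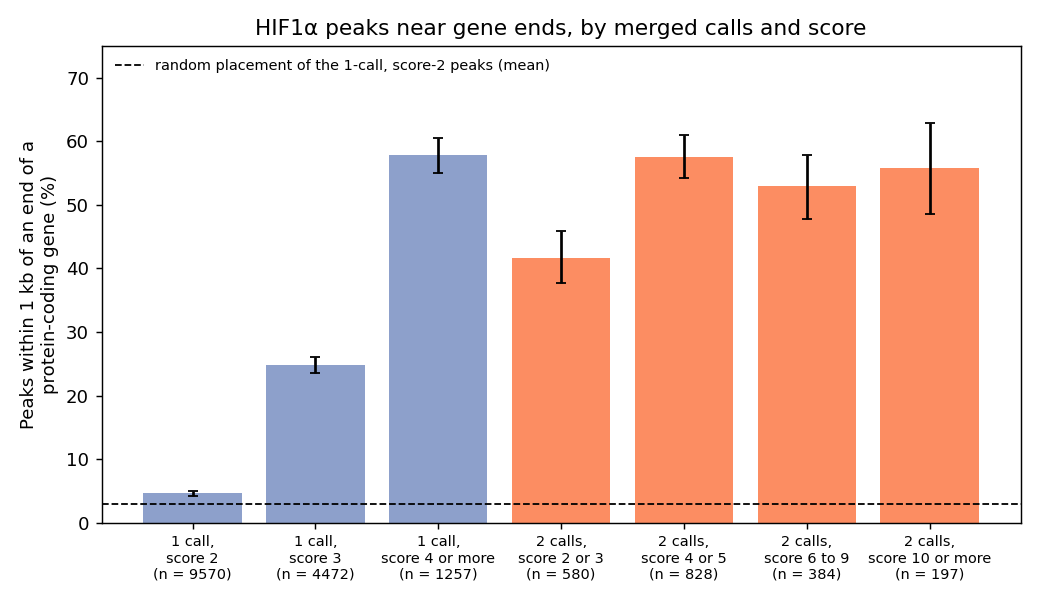
Share of peaks within 1 kb of an end of a protein-coding gene, in percent, by merged calls and deposited score; blue bars are peaks of 1 call, orange bars peaks of 2 merged calls, error bars are exact 95% intervals and the dashed line is the mean of random placements of the 1-call, score-2 peaks (3.0%). The share rises from 4.62% at a score of 2 to 57.8% at 4 or more among peaks of 1 call, and lies between 41.7% and 57.6% for peaks of 2 calls.

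The peak list as a whole was described by score, chromosome and clustering. The score ranged from 2 to 3315, and 9685 peaks (56%) had the lowest score of 2. The median score was 2 for peaks of 1 call and 4 for peaks of 2 calls. Of the 207 peaks with a score of 10 or more, 197 were of 2 calls. The highest score, 3315, belonged to a peak inside Chl1 on chromosome 6 (103649152 to 103649252), 83.8 kb from the nearest end of that gene. The next highest were 169 (61.1 kb from Axin2), 167 (76.8 kb from Chd2), 162 (282 kb from Pex2), 157 (487 bp from Narf) and 157 (inside Filip1l). The remaining 4 of the top 10 were 129 (inside Cdk8), 122 (mitochondrial genome), 116 (171 kb from Samd9l) and 109 (Eno1). Of these top peaks, only those at Narf and Eno1 lay within 1 kb of a protein-coding gene end. Among all peaks of 2 calls with scores of 10 or more, 55.8% did. No filter for repeats or artefact-prone regions was applied here, and input levels were not analysed. The highest scores therefore need not reflect HIF1α binding.

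Autosomes carried between 6.03 (chromosome 7) and 7.82 (chromosome 17) peaks per Mb of the span from the first to the last annotated gene. Chromosome X carried 403 peaks, or 2.41 per Mb. Its share of peaks was 2.33% (interval 2.11 to 2.57%) against 6.3% of the span, with an adjusted p of 7.8e-131 (two-sided exact binomial test, Benjamini-Hochberg over 21 chromosomes). Chromosome Y carried 114 peaks, 1.26 per Mb (adjusted p = 4.7e-129, exact binomial test). Of the 19 autosomes, 10 had an adjusted p under 0.05, with far smaller departures (exact binomial test). Shares of peaks add to a whole, so the low shares of X and Y by themselves raise those of autosomes. This count is therefore not a separate finding about autosomes. On chromosome Y, 34 of the 114 peaks were of 2 calls. Their density was 0.374 per Mb, against 0.215 on X and 0.52 to 1.32 on autosomes. Protein-coding genes with most peaks within 50 kb were Gm21190 and Gm21083 (14 each), Gm10354 (13), Zfp982 (12), Gm17019 (11), Gm15319 and Sbno2 (10 each), and Speer4d, Nfix and Gm38510 (9 each). Gm10354, Gm17019, Gm21190, Gm21083 and Speer4d lie on chromosome 5 between 14974144 and 15623864. The 50 kb windows of neighbours such as Gm21190 and Gm21083 overlap, so 1 peak can count for both. The peaks nearest to the genes with most peaks scored 2 to 5 and were of 1 call, except at Gm15319. Read mappability at these loci was not examined.

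**Figure D4:**
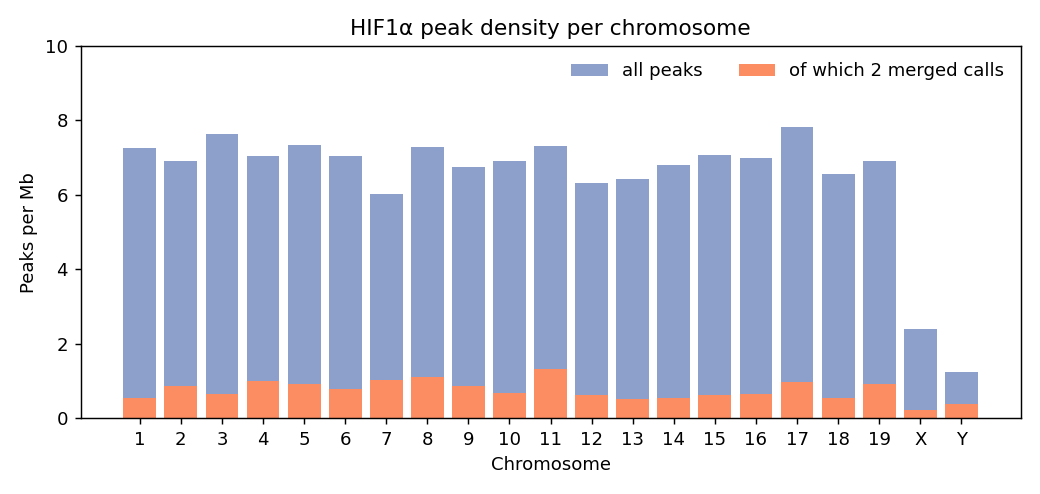
Peaks per Mb of each chromosome, over the span from its first to its last annotated gene; the full bar is all peaks and the orange part is peaks of 2 merged calls. Autosomes lie between 6.03 and 7.82 peaks per Mb, chromosome X at 2.41 and chromosome Y at 1.26.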

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

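The single peak on the mitochondrial genome drew attention because it lies in sequence that no gene comparison used. It spans positions 16084 to 16184, beyond the last annotated mitochondrial gene end at 15422, and has a score of 122 from 1 call. Of the 10 peaks of 1 call with a score of 10 or more, it is the one that reached the top 10 of the whole list. The input level at this position was not analysed here, so the value is given without an explanation.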

How the results depend on the processing

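The shares of hypoxia, glycolysis and olfactory receptor genes near peaks kept their direction and their side of the threshold under all 8 alternative settings. The concentration of peaks near gene ends held under all 7 alternatives, at 1.54 to 8.86 times random placement. Settings using peaks of 2 calls, peaks inside genes and the matched background were chosen after seeing the data, as were, for location, scores of at least 3 and random placement by moving each peak 50 to 500 kb. The peak count was 7604 at scores of at least 3 and 1989 for peaks of 2 calls, by construction. For the other changes below the cause was not tested. Leaving out a replicate was not run, since calls are not marked by replicate. No paired analysis was possible because the input and the pulldowns share fewer than 2 replicate numbers and the list is merged. Motif settings, any-transcript starts and the CpG-matched background were not run for want of sequence and transcripts. Of 152 list values, 110 kept direction and call.

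The stress response list stayed above other genes but lost its call at 1 kb (33.3% against 16.2%), at 50 kb (83.3% against 63.5%), with 2 calls (16.7% against 7.71%), with 2 calls at 1 kb (16.7% against 5.53%) and with peaks inside genes counted (53.3% against 32.6%). Calls appeared at 1 kb for autophagy (43.5%), ribosomal protein (39.3%) and angiogenic genes (0%, lower). They also appeared for liver genes at 50 kb (30.0%, lower) and by nearest gene (5.0%, lower), for ribosomal protein genes at scores of at least 3 (42.9%) and with the matched background (42.9%), and for autophagy genes with 2 calls at either window (26.1%).

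Lists with no call under either setting changed side of the background 28 times. At 1 kb these were p53 (13%), cardiac factor (14.3%), sarcomere (6.67%) and erythroid genes (11.1%). At 50 kb they were cardiac factor (57.1%), endothelial (65.0%) and epicardial genes (64.3%). By nearest gene they were respiratory chain (30.8%), fatty acid (28.0%), endothelial (40.0%), epicardial (35.7%), erythroid (27.8%), angiogenic (37.0%), ribosomal protein (32.1%) and neuronal genes (50.0%). At scores of at least 3, erythroid genes did so (16.7%). With 2 calls, cardiac factor (0%), erythroid (5.56%) and liver genes (15%) did so. With 2 calls at 1 kb, p53 (4.17%), cardiac factor (0%), sarcomere (0%), epicardial (7.14%) and liver genes (10.0%) did so. With peaks inside genes counted, cardiac factor (32.1%), epicardial (35.7%), erythroid (27.8%) and neuronal genes (45.0%) did so. Most of these lists hold 14 to 32 genes, so 1 gene moves a share by several points.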

Other observations

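The glycogen list, the Mrpl comparison, the scan of gene families, the comparison with ribosomal protein genes, the place of low-scoring peaks against gene ends, and the thinning of autosomal scores were tests chosen after the result was seen. Glycogen metabolism genes lay near peaks of 2 calls in 9 of 26 cases (34.6%) against 7.69% of other genes (p = 8.92e-05, two-sided Fisher exact test). Because the list was drawn up after some of its members had been seen near peaks, this is a hypothesis and not independent evidence. Members near such peaks included Gbe1, Gys1, Pgm1, Ppp1r3c and Pygl. Ppp1r3c, which encodes a subunit that targets a phosphatase to glycogen, had a peak of score 28 at 281 bp from its end. Gys1 (glycogen synthase) had one of score 15 at 273 bp and Pygl (glycogen phosphorylase) one of score 13 at 112 bp.

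Genes of the large mitochondrial ribosomal subunit (Mrpl) lay within 5 kb of peaks of 2 calls in 18 of 49 cases (36.7%), against 14 of 90 (15.6%) cytosolic ribosomal protein genes (p = 0.00621, two-sided Fisher exact test). The family was picked from the scan of the same peaks described next, so this p is not independent evidence. In a scan of 376 symbol prefixes with at least 8 genes, 7 had an adjusted p under 0.05 for peaks of 2 calls within 1 kb (Fisher exact test). Higher shares than the 5.54% of all protein-coding genes were seen for Mrpl (16 of 49), Pcdhga (12 of 12, a cluster in which genes share an end), Vps (8 of 35) and Kmt (4 of 8). Genes of the small mitochondrial ribosomal subunit (Mrps) did not pass, at 4 of 29 (13.8%, adjusted p = 0.657, Fisher exact test). Lower shares were seen for Olfr (0 of 1109), Vmn (0 of 352) and Gm (15 of 1323). Among genes of other kinds, 9.43% of 403 tRNA genes (interval 6.76 to 12.7%) and 3.09% of 1228 microRNA genes (interval 2.2 to 4.22%) lay within 1 kb of a peak, against 1.35% and 1.3% in 20 random placements. For snRNA genes the share was 4.41% against 1.33%, for snoRNA genes 1.35% against 1.34%, and for pseudogenes 1.57% against 2.03% in random placements. A single peak can count for several neighbouring genes. The intervals for tRNA and microRNA genes treat genes as independent and may therefore be too narrow. Mir210, a microRNA induced by low oxygen, had a peak of 2 calls with a score of 29 at 437 bp (chromosome 7, 141221878 to 141221982). It was not named by the fixed rule, and is 1 of 15 microRNA genes within 1 kb of a peak of 2 calls. The highest score among these was 51, at Mir6236 (30 bp).

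The higher share of hypoxia and glycolysis genes near peaks was set against gene layout and against widely transcribed genes, a stand-in for open promoters. Among genes matched on length and gene density, 25.4% would be near a peak, whereas 39 of the 47 genes (83.0%) were (exact stratified p = 6.5e-17), which argues against layout as the whole cause. Cytosolic ribosomal protein genes, which most cells transcribe at high levels, were near peaks in 12 of 28 cases (42.9%). This was fewer than the 47 genes (p = 0.000665, two-sided Fisher exact test), which argues against wide transcription alone. Matched on layout, 18.8% of ribosomal protein genes would be near a peak, against 25.4% of the 47. Promoter openness itself was not measured and stays open. With peaks of 2 calls the counts were 37 of 47 and 6 of 28 (p = 2.03e-06, Fisher exact test). The specificity of the antibody stays open, and no biological explanation was tested, since the design has no hearts lacking HIF1α.

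Peak density on chromosome X was 0.344 times that of autosomes (interval 0.311 to 0.38). Fewer genes on X do not account for this: over 5 kb from every protein-coding gene end the ratio was 0.362 (interval 0.323 to 0.404), and 93 of 963 X genes (9.66%) were near a peak against 24.9% of autosomal genes. The ratio was 0.479 at a score of 2, 0.178 (interval 0.135 to 0.229) at 3 and 0.171 (interval 0.116 to 0.243) at scores of 4 or more, a fall opposite to the forecast written for a single X copy in male embryos with a low calling threshold; over 5 kb from gene ends it was 0.443 (interval 0.39 to 0.5) at a score of 2 and 0.323 (interval 0.19 to 0.513) at 4 or more, with overlapping intervals. That forecast was wrong in direction: if scores were counts, which the file does not say, keeping 50% of the autosomal counts would give 0.527, 0.26 and 0.235 at these scores and keeping 75% would give 0.818, 0.578 and 0.547, so a weaker signal also gives a fall. These sizes match in part. For all peaks, keeping 50% gives values inside the observed intervals at a score of 2 (0.426 to 0.536) and at 4 or more. Over 5 kb from gene ends the same holds, at 0.419 and 0.234. Against this, 0.26 lies above the observed interval at a score of 3, and the values for 75% lie above all observed ones. Within 5 kb of gene ends, keeping 50% would give 1.41 at a score of 2 where 0.877 (interval 0.633 to 1.19) was observed. At 4 or more it would give 0.236 there, inside the observed interval (0.0763 to 0.246). With the unit of the score, embryo sex and read mappability unknown here, a single X copy cannot be told apart from other causes.

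Peaks of 1 call with a score of 2 were weighed as calls placed by chance. None of the 47 hypoxia and glycolysis genes lay within 5 kb of such a peak, against 5.32% of other genes (p = 0.179, two-sided Fisher exact test). For peaks of 1 call with scores of 4 or more, it was 1 of 47 (2.13%) against 4.99% (p = 0.731, two-sided Fisher exact test). Yet 57.8% of those higher-scoring peaks lay within 1 kb of a protein-coding gene end. The list test therefore cannot tell chance placement from peaks at gene ends, and it leaves chance open. Of the peaks of 1 call with a score of 2, 4.62% lay within 1 kb of a protein-coding gene end. This was 1.54 times the share of random placements (3.0% ± 0.174, SD). The difference (one-sided permutation p = 0.001, the smallest possible) argues against even placement as the whole cause. Chance placement of part of these peaks, and background reads that collect at open promoters, stay open. No biological explanation was tested for this group.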
